A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

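Total RNA from 3 cultures of a wild-type strain and 3 cultures of a strain with the H2B K123R substitution was labelled with biotin after cDNA and cRNA synthesis by the array maker's manual and hybridised to Affymetrix S98 yeast arrays, 1 array per sample, per the labels' protocols. Groups and replicate numbers were taken from the sample titles and characteristics. The cultures were inoculated in triplicate per the labels; whether they came from separate starter cultures is not given in the sources used here, so p-values measure the spread between these 3 cultures.

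The deposited values are probe set intensity values on a linear scale, which the authors' processing had already scaled: the mean of each array's values after trimming 2% at each end was 500.4 to 500.5. The summarization software and its settings are not given in the sources used here, and detection calls were not used. The number of arrays limits the precision. Of the 9335 probe sets, 60 controls were set aside and 9275 were tested. The platform annotation, of which the symbols were checked through gene identifiers against the gene table of the R64 assembly, paired 6504 of the tested probe sets with 1 gene, 328 with several and 2443 with none; no symbol needed updating, and no gene was named from a probe set with several. This gave 5656 genes, 315 of them with more than 1 probe set. The genome build behind the array design is not given in the sources used here, so no coordinates are printed; R64 served for names and gene order.

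Signals were used as log2(signal + 16). Array medians differed by 0.0924 on this scale, under the limit of 0.5 set for adding a quantile step, so none was added. Differences between H2B K123R and wild type were tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over the 9275 probe sets and a threshold of 0.05. Fold changes are on the log2(signal + 16) scale. Gene lists were tested with camera at a preset correlation of 0.01, over 5656 genes with 1 probe set each, the one with the highest mean over the 6 arrays; lists needed at least 4 measured members and p-values were adjusted over the 34 lists. No list was called by camera with an estimated correlation. Fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes, called 13 lists, including 10 of the 16 called by camera. A list's median was also set against 10000 random lists in which each member was replaced by 1 of the 60 other genes nearest in mean level. The list's place among them is given as a percentile, and 12 of the 16 lists lay outside the middle 95%. Glycolysis, alpha-specific, ergosterol and purine genes did not. Each random member was drawn independently, so a list whose genes vary together lies outside more easily, and the percentile does not allow for that. This matching replaced, after its result was seen, one by level classes that could draw the list's own members.

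The lists covered histones, H2B ubiquitination and associated factors, silencing and histone chaperone factors, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, general stress, heat shock chaperones, glycolysis, glucose-repressed genes, hexose transporters, the tricarboxylic acid cycle and respiration, phosphate starvation, galactose, a- and alpha-specific genes, haploid-specific and pheromone-induced genes, sporulation, 3 cell cycle phases, Gcn4 targets, sulfur amino acids, purines, iron, the proteasome, DNA damage, stationary phase, autophagy, ergosterol, cell wall, flocculins and seripauperins, selectable markers, and the 10 protein-coding genes nearest each chromosome end. Some genes are in more than 1 list. The lists, the tests of the comparison and the rule for named genes were fixed before the data were examined. The level matching was not.

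Named genes were chosen by rule. They were the 10 largest rises and 10 largest falls among genes that passed, with a probe set not of a family, rules-dropped or incomplete type, no overlap between the groups, and a higher group mean above the median of all probe sets. The H2A and H2B genes and the a- and alpha-specific genes were always named. For each list called by camera, the 4 members with the smallest p in its direction were named, whether or not they passed; for other lists, the member with the smallest p if it passed. TDH1 and PIR3, which moved against their lists, and the small RNA genes, neighbouring genes and second probe sets given were named after their values were seen.

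The procedure was tested on simulated data: of 100 probe sets changed by 1.5-fold 38% were recovered, of 100 changed by 2-fold 71% were, and 2.68% of the calls were false. A list shifted by 0.3 was called and no other list was. The simulated genes varied independently of each other and no simulated array stood apart. The simulation therefore does not show how many false calls arise where genes vary together. The replicate numbers are from the sample titles, and the labels do not say what they mark. Deviations from the group means of same-numbered arrays correlated at 0.318, 0.382 and 0.0527, and a pairing needed all 3 above 0.1, so the fit has no block. Those of differently numbered arrays correlated between -0.392 and 0.0230, so a pairing of some of the arrays is not excluded. Alternatives were a block on the replicate number, pseudocounts of 1 and 64, filters on mean level at the 25th percentile and the median, quantile normalization, median alignment, no variance trend, a robust trend, array weights, leaving out each of the 6 arrays, the mean of a gene's probe sets, and the other list tests; cyclic loess was added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.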

Results

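RNA levels were measured in budding yeast (Saccharomyces cerevisiae) that carried either wild-type histone H2B or H2B with the K123R substitution, which replaces the lysine that is the site of H2B monoubiquitination with arginine. Early stationary phase cultures were diluted into rich medium at an optical density of 0.3 and grown at 30 degrees for 7 hours to an optical density of 2, in triplicate for each strain. Total RNA of each culture was hybridised to 1 Affymetrix S98 array, a single-channel oligonucleotide array, which gave 3 wild-type and 3 H2B K123R arrays with 9335 probe sets each. The median signal per array lay between 131 and 139. Log2 signals correlated at 0.992 to 0.995 between wild-type arrays and at 0.991 between H2B K123R replicates 2 and 3. H2B K123R replicate 1 stood apart, with correlations of 0.958 and 0.969 to the other arrays of its group and a 99th percentile of signal of 8652, against 10221 to 11395 on the other 5 arrays. Its ratio of 3' to 5' actin control signal was 1.98, against 1.40 to 1.59 elsewhere. Each strain has its own strain name, so any further difference between the strains was compared together with the mutation.

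The comparison asked how gene expression differed between H2B K123R and wild-type cells resuming growth from early stationary phase. ARG1, which encodes argininosuccinate synthase, rose 5.70-fold from 361 ± 27.2 to 2129 ± 48.3 (mean ± SD, n = 3 in each group here and below; limma adjusted p = 0.000179). YNR064C, an epoxide hydrolase gene, rose from 11.6 ± 2.70, within the range of the mouse control probe sets, to 156 ± 18.2 (adjusted p = 0.00117); its log2 difference was 1.54 with a pseudocount of 64 and 3.66 with one of 1, so no fold is given. HPF1, a cell wall mannoprotein gene, rose 4.51-fold from 538 ± 57.5 to 2475 ± 98.8, and FIT2, a cell wall mannoprotein gene of siderophore-iron uptake, rose 3.05-fold from 292 ± 13.2 to 924 ± 62.2. GSC2, which encodes a catalytic subunit of beta-glucan synthase, rose 3.81-fold from 172 ± 16.2 to 703 ± 95.6 on the brightest of its 7 probe sets. Its other probe sets did not pass the test, with adjusted p between 0.332 and 0.947, and the mean of its probe sets was not called (log2 difference 0.67, adjusted p = 0.470). ECM13 (45.0 to 204) and FMP46 (286 to 964) rose 3.63-fold and 3.23-fold. ARO5 (67.9 to 237), SPS19 (71.2 to 240), a peroxisomal fatty acid oxidation gene, and YJR079W (65.5 to 214) rose between 2.85-fold and 2.96-fold. The dimmer probe set of YJR079W did not pass, with means of 14.4 and 14.2 and an adjusted p of 0.908. Folds are on the log2(signal + 16) scale, which understates the change of dim genes.

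Under the same naming rule, which leaves out dim genes and probe sets of shared types, the largest falls were smaller in size than the largest rises. AFB1, which encodes the a-factor barrier protein, fell 2.36-fold from 173 ± 17.7 to 64.5 ± 13.3 (limma adjusted p = 0.0164). ALE2 fell 2.27-fold from 2173 ± 72.8 to 949 ± 74.3 (adjusted p = 0.00237), and PLB2, a phospholipase B gene, fell 2.26-fold from 877 ± 85.6 to 380 ± 40.4. ATF2, an alcohol acetyltransferase gene, went from 433 to 186, and EEB1, an ethyl ester synthase gene, from 143 to 64.6. SST2, whose product switches off the G protein of the pheromone pathway, fell 2.01-fold from 624 ± 52.3 to 302 ± 22.4. PAD1, a phenylacrylic acid decarboxylase gene, fell 2.00-fold from 625 ± 43.3 to 305 ± 16.9. The remaining members of this group were SVL3 (986 to 448), ERC1 (563 to 259) and PNS1 (150 to 63.6), with falls between 2.09-fold and 2.19-fold. The 20 genes kept their calls without H2B K123R replicate 1 or without replicate 2. Calls were left for 14 of them without wild-type replicate 1, for 12 without wild-type replicate 2, for 8 without wild-type replicate 3 and for 13 without H2B K123R replicate 3; YNR064C, ARG1, HPF1, GSC2, ECM13, FMP46, FIT2 and ALE2 passed in every one of these fits.

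**Figure D1:**
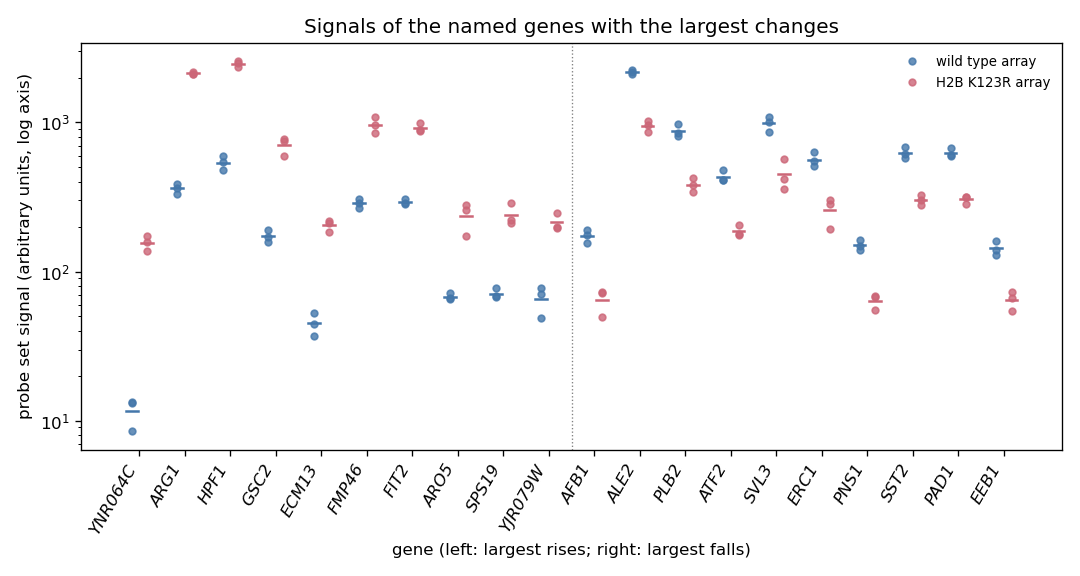
Probe set signal (arbitrary units, log axis) of the 10 largest rises and 10 largest falls among genes of the naming rule on each of the 3 wild-type (blue) and 3 H2B K123R (red) arrays; points are arrays and short lines are group means. The rule took genes that passed, whose groups do not overlap, with a higher mean above the median of all probe sets and no probe set of a family, rules-dropped or incomplete type; ARG1 means are 361 and 2129, and ALE2 means are 2173 and 949.

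In all, 620 of 9275 probe sets (6.68%) passed limma's test at an adjusted p under 0.05, 391 of them higher and 229 lower in H2B K123R. Of these, 105 changed at least 2-fold, 67 higher and 38 lower. Counted with 1 probe set per gene, 508 of 5656 genes passed, 343 higher and 165 lower. Of the 180 lower probe sets that name 1 gene, 45 were for tRNA genes, many of which are not independent of each other. An unadjusted p under 0.05 was found for 2307 probe sets. The arrays of the groups did not overlap for 3012 probe sets (32.5%, where chance gives 10%), among them all 620 that passed. With a block on the replicate number 307 probe sets passed. The number of calls depended on the arrays used: it was 59 without wild-type replicate 1, 42 without wild-type replicate 2, 22 without wild-type replicate 3 and 70 without H2B K123R replicate 3. It was 1023 without H2B K123R replicate 1, of which 541 (52.9%) were higher, against 63.1% higher on all arrays.

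Amino acid biosynthesis genes were higher in H2B K123R. Of 52 measured targets of Gcn4, the activator of amino acid biosynthesis, 14 rose and none fell (18 when adjusted over the list alone), with a median log2 difference of 0.19. Besides ARG1, these included HIS4 (1669 ± 124 to 4067 ± 168), HIS3 (2899 ± 80.7 to 5747 ± 274) and ARG4 (1423 ± 106 to 3256 ± 292), which rose 2.43-fold, 1.98-fold and 2.27-fold. A dimmer probe set of HIS3 also rose (adjusted p = 0.00370). HIS3 is also on the list of selectable markers, and whether the strains carry it as a marker was not tested. The list passed camera with a preset correlation (adjusted p = 0.00695), but not with an estimated correlation (adjusted p = 0.438). Sulfur amino acid genes rose too, 12 of 26 with none falling (15 up and 1 down when adjusted over the list alone) and a median of 0.54. Among them were MET2 (87.0 to 263), MET14 (460 to 1176), MET5 (558 to 1363) and MET10 (147 to 370), which act in sulfate assimilation and methionine synthesis and rose between 2.37-fold and 2.70-fold. This list had a camera adjusted p of 0.000104, and an adjusted p of 0.438 with an estimated correlation. Without wild-type replicate 1, 2 or 3, the members of the Gcn4 list that passed numbered 4 each time, and those of the sulfur list 6, 4 and 2; without H2B K123R replicate 3 they numbered 5 and 4.

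Genes of the general stress response and of stationary phase were higher as well. Of 50 measured targets of Msn2 and Msn4, the general stress activators, 11 rose and none fell (24 when adjusted over the list alone), with a median log2 difference of 0.38 and a camera adjusted p of 1.72e-05. The adjusted p was 0.438 with an estimated correlation. HSP12, a small membrane heat shock protein gene, rose 1.87-fold from 774 ± 46.6 to 1461 ± 86.0, GPH1, glycogen phosphorylase, rose from 139 to 261, HSP30 from 847 to 1392 and TFS1 from 413 to 642. Of 22 stationary phase and quiescence genes, 7 rose (14 when adjusted over the list alone), with a median of 0.52 and a camera adjusted p of 4.17e-05, against an adjusted p of 0.369 with an estimated correlation. SNZ1, a vitamin B6 synthesis gene, rose 2.17-fold from 162 to 371, SPG5 rose 2.15-fold from 297 to 663 and the polyubiquitin gene UBI4 rose 1.73-fold from 481 to 845. Without wild-type replicate 3 no member of either list passed, without wild-type replicate 1 or 2 or H2B K123R replicate 3 at most 2 did, and without H2B K123R replicate 1 the numbers were 14 and 10.

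Of 34 proteasome genes, 5 rose and none fell (14 when adjusted over the list alone), and all 34 differences were positive, with a median of 0.31. RPT1, an ATPase subunit gene, rose 1.45-fold from 1945 ± 132 to 2832 ± 189, RPN2 from 1363 to 1839, PRE4 from 1760 to 2259, and UBP6, a proteasome-associated deubiquitinase gene, from 922 to 1463. The camera adjusted p was 4.17e-05, the adjusted p was 0.574 with an estimated correlation and the fry adjusted p was 0.0590. The list's mean log2 signal was 10.79 on the array of H2B K123R replicate 1, 10.47 and 10.59 on the other mutant arrays and 10.24 to 10.34 on the wild-type arrays, and the median difference was 0.21 without replicate 1. Of 20 autophagy genes, 3 rose (8 when adjusted over the list alone), with a median of 0.30, a camera adjusted p of 0.0157 and an adjusted p of 0.438 with an estimated correlation. These 3 were ATG14, at low signals of 12.7 and 24.0, and the vacuolar protease genes PEP4 (4265 to 5323) and PRB1 (726 to 987), which serve vacuolar protein breakdown in general. Autophagy was not called among genes above the median level (adjusted p = 0.0618). None of the 3 genes passed with a block on the replicate number. No gene of these lists passed without wild-type replicate 1, 2 or 3 or H2B K123R replicate 3, and without H2B K123R replicate 2 no autophagy gene passed.

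Of 50 genes of the tricarboxylic acid cycle and respiratory chain, 9 rose and none fell (15 when adjusted over the list alone), with a median of 0.19, a camera adjusted p of 0.00695 and an adjusted p of 0.438 with an estimated correlation. LSC2, a succinyl-CoA ligase subunit gene, rose 1.63-fold from 378 ± 4.92 to 629 ± 55.5, the succinate dehydrogenase genes SDH2 and SDH3 rose from 608 to 936 and from 743 to 1109, and CYC7, a cytochrome c gene, rose from 33.9 to 82.9. Of 67 mitochondrial ribosomal protein genes, 5 rose (9 when adjusted over the list alone), with a median of 0.26, a camera adjusted p of 0.000104, an adjusted p of 0.579 with an estimated correlation and a fry adjusted p of 0.0811. The largest among its named members was MRPL51 (505 to 818), followed by MRPL49 (367 to 582), MRPL33 (637 to 930) and MRP1 (550 to 772). The mean log2 signal of the mitochondrial ribosomal protein genes was 8.52 on the array of H2B K123R replicate 1, 8.22 and 8.27 on the other mutant arrays and 8.03 to 8.10 on the wild-type arrays, and their median difference was 0.16 without replicate 1. No member of either list passed without wild-type replicate 1, 2 or 3 or H2B K123R replicate 3. The glucose-repressed genes of gluconeogenesis and acetate use were not called (camera adjusted p = 0.0673), although 3 of 28 rose (4 members passed when adjusted over the list alone), and the list was called without H2B K123R replicate 1 (adjusted p = 0.0136), with the mean of the probe sets of a gene (0.0364) and by fry (0.00462). JEN1, the lactate permease gene, read 3.64 ± 1.98 in wild type, within the range of the mouse control probe sets, and rose to 39.3 ± 11.4. Without wild-type replicate 1, 2 or 3 or H2B K123R replicate 3, at most 1 gene of this list passed.

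Cytosolic ribosomal protein genes were slightly lower as a group. None of the 81 measured genes passed on its own, over all probe sets or when adjusted over the list alone, 77 differences were negative, and the median log2 difference was -0.19. The camera adjusted p was 1.71e-09, the adjusted p was 0.438 with an estimated correlation and the fry adjusted p was 0.0811. RPL24A read 7722 ± 484 in wild type and 6294 ± 219 in H2B K123R (adjusted p = 0.0654), RPS28B 11847 and 9712, RPS7B 6971 and 5625, and RPL30 6883 and 5560; a dimmer probe set of RPS7B passed (adjusted p = 0.0404). The list's mean log2 signal was 12.64 on the array of H2B K123R replicate 1, whose bright signals were compressed, and 12.80 and 12.84 on the other mutant arrays, against 12.90 to 12.95 on the wild-type arrays. Its median was -0.12 without that array. After quantile normalization the median was -0.03 and the list was not called (adjusted p = 0.0802), nor was it after cyclic loess (median -0.06, adjusted p = 0.0540). Of 19 genes of glycolysis and fermentation, PFK1, a phosphofructokinase gene, fell from 5398 to 4265, GPD1, which serves glycerol synthesis, fell from 1822 to 1253, and 1 other gene rose, TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, with a log2 difference of 0.49. When adjusted over the list alone, 3 passed upward and 4 downward. ENO2 read 15693 and 12336 and PFK2 6651 and 5518, and neither passed. The list's median was -0.22, with a camera adjusted p of 0.00586, an adjusted p of 0.574 with an estimated correlation and a fry adjusted p of 0.250. It lay within the middle 95% of level-matched lists (percentile 9.27) and was not called without H2B K123R replicate 1 (median -0.10, adjusted p = 0.143), after quantile normalization (-0.03, 0.380), after cyclic loess (-0.05, 0.424) or with array weights (-0.14, 0.0529). No glycolysis gene passed without wild-type replicate 1, 2 or 3 or H2B K123R replicate 3.

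Of 7 a-specific genes, 2 fell and none rose (3 fell when adjusted over the list alone): MFA1, an a-factor gene, fell 1.53-fold from 3612 ± 456 to 2356 ± 201 on a probe set of a type shared by gene families, while its other probe set did not pass (344 and 245, adjusted p = 0.134), and BAR1, the protease that degrades alpha-factor, fell 1.32-fold from 1846 ± 78.2 to 1395 ± 84.1. STE2, the alpha-factor receptor gene, read 1365 and 1115 (adjusted p = 0.0876), STE6 573 and 501, AGA2 519 and 457, MFA2 5538 and 5241 and ASG7 56.1 and 71.3, none of which passed. The small difference in MFA2 had the opposite sign after quantile normalization and cyclic loess. The camera adjusted p of the a-specific list was 0.0118, and its adjusted p was 0.438 with an estimated correlation. Of 4 alpha-specific genes, the alpha-factor genes MF(ALPHA)1 (44.4 ± 5.39 to 79.4 ± 6.52) and MF(ALPHA)2 (40.8 ± 1.16 to 71.6 ± 1.93) rose 1.58-fold and 1.54-fold (3 passed when adjusted over the list alone), while SAG1 read 163 and 214 and STE3 38.0 and 46.7. This list had a median of 0.49, a camera adjusted p of 0.0185 and an adjusted p of 0.438 with an estimated correlation, and its median lay within the middle 95% of level-matched lists (percentile 96.1). Of 28 haploid-specific and pheromone-induced genes, 6 fell and none rose (6 when adjusted over the list alone), with a median of -0.17. The list had a camera adjusted p of 0.000851, an adjusted p of 0.438 with an estimated correlation and a fry adjusted p of 0.0811. Besides SST2, these included FUS3, the mitogen-activated protein kinase gene of the pathway (409 to 235; not called with the mean of its probe sets), AGA1, an agglutinin subunit gene (745 to 486), and PRM4 (181 to 110). When any single array other than H2B K123R replicate 1 was left out, no a- or alpha-specific gene passed, and at most 2 of the haploid genes did. The a-specific list was not called with array weights (adjusted p = 0.0564). With a block on the replicate number no a- or alpha-specific gene passed. Of 43 early and middle sporulation genes 3 rose, with SPS19 the strongest, and 2 fell (5 members when adjusted over the list alone), and the list was not called (camera adjusted p = 0.577). At most 1 sporulation gene passed without wild-type replicate 1, 2 or 3 or H2B K123R replicate 3.

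Of 26 genes expressed from mitosis into G1, many of which act in separating daughter from mother cells, 3 fell and 1 rose (7 and 2 when adjusted over the list alone), with a median of -0.35, a camera adjusted p of 5.65e-05 and an adjusted p of 0.369 with an estimated correlation. The cell wall hydrolase genes DSE2 and CTS1 fell 1.56-fold and 1.41-fold, from 2999 ± 19.2 to 1918 ± 113 and from 5173 ± 202 to 3658 ± 272, and EGT2 fell from 1424 to 1078. TEC1, a transcription factor gene, read 1035 and 721 (adjusted p = 0.0517). The gene that rose was PIR3, a cell wall protein gene, with a log2 difference of 0.87. The list's mean log2 signal was 9.01 on the array of H2B K123R replicate 1, 9.23 and 9.16 on the other mutant arrays and 9.36 to 9.40 on the wild-type arrays. No gene of this list passed without wild-type replicate 1, 2 or 3, and 1 did without H2B K123R replicate 3. The list of G1 and S phase genes was not called (camera adjusted p = 0.0609); 4 of 33 fell and 2 rose (9 when adjusted over the list alone), and CLN1, a G1 cyclin gene, fell 1.59-fold from 403 ± 14.0 to 247 ± 4.02. It was called without wild-type replicate 1 (adjusted p = 0.0477), without H2B K123R replicate 2 (0.0430), after quantile normalization (0.0374) and with the mean of the probe sets of a gene (0.0364). Of 22 G2 and M phase genes, 2 rose and 1 fell (6 when adjusted over the list alone), without a call for the list (camera adjusted p = 0.334); CDC20, an activator of the anaphase-promoting complex, rose from 401 to 551. No gene of the G1 and S or G2 and M lists passed without wild-type replicate 1, 2 or 3 or H2B K123R replicate 3.

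Of 25 ergosterol genes, ERG5 fell 1.48-fold from 650 ± 40.5 to 434 ± 34.8 and ERG11 fell 1.29-fold from 6019 ± 278 to 4656 ± 349, and none rose (5 down and 1 up when adjusted over the list alone). UPC2, the sterol-responsive activator gene, read 54.1 and 31.8, and ERG26 943 and 722, without passing. The median of the ergosterol list was -0.06, or -0.13 without H2B K123R replicate 1. Its camera adjusted p was 0.0190, its adjusted p 0.438 with an estimated correlation and its fry adjusted p 0.0832. Of 16 purine genes, 3 fell (3 when adjusted over the list alone): ADE8 fell 1.96-fold from 1046 ± 89.0 to 530 ± 83.5, and the IMP dehydrogenase genes IMD2 and IMD3, which serve guanine nucleotide synthesis, fell from 4713 to 2822 and from 5279 to 3999. IMD2 and IMD3 are near-identical in sequence and their probe sets are of a type shared by gene families, so their signals cannot be assigned to either gene with certainty. The other 2 probe sets of IMD2, of the same type, also fell (adjusted p = 0.0164 and 0.0117). IMD4 read 6282 and 5558 on one probe set and 4552 and 2825 on the other (adjusted p = 0.136 and 0.126), and neither passed. The median of the purine list was -0.11 and its camera adjusted p 0.0190, with an adjusted p of 0.438 with an estimated correlation. Both medians lay within the middle 95% of level-matched lists (percentiles 12.3 for ergosterol, or 0.95 without H2B K123R replicate 1, and 7.78 for purine). Neither list was called after quantile normalization (adjusted p = 0.0740 for ergosterol and 0.0523 for purine) or cyclic loess (0.140 and 0.0919), and the purine list was not called without H2B K123R replicate 1 (0.0844). No ergosterol gene passed without wild-type replicate 1, 2 or 3 or H2B K123R replicate 3, and of the purine genes at most 1 did. Neither ERG5 nor ERG11 passed with a block on the replicate number.

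**Figure D2:**
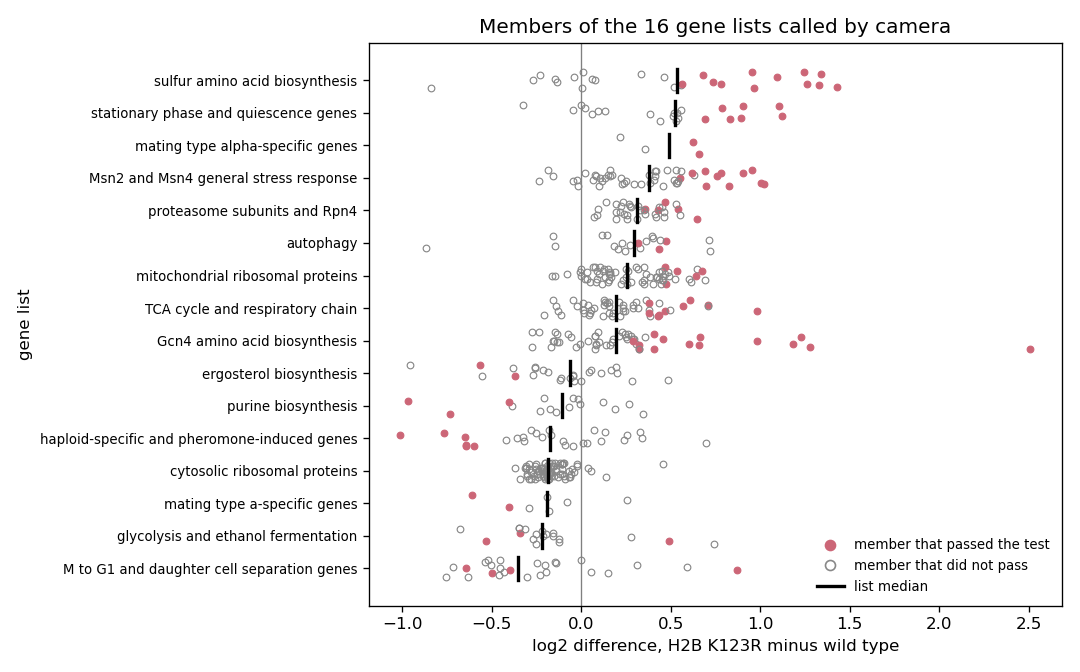
Log2 difference between H2B K123R and wild type (horizontal axis) for each measured member of the 16 gene lists called by camera with a preset correlation (vertical axis); filled points passed limma's test, open points did not, and black bars are list medians. The medians lie between -0.35 for the genes of mitosis to G1 and 0.54 for the sulfur amino acid genes, and every ribosomal protein gene is an open point.

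Of the histone genes themselves, HTB1, an H2B gene, read 5836 ± 358 in wild type and 4560 ± 458 in H2B K123R (log2 difference -0.36, adjusted p = 0.0739), which did not pass. HTB2, the other H2B gene, read 6.78 and 4.14, within the range of the mouse control probe sets (0.922 to 18.3) in both groups. Which histone genes the strains carry is not given in the sources used here, so a low HTB2 level was not told from absence of the gene. These probe sets measure transcript level and do not read the substitution. HTA1 and HTA2 had no probe set of their own. No member of the histone list passed over all probe sets, and 1 of 5 did when adjusted over the list alone (camera adjusted p = 0.238). Of 24 genes for H2B ubiquitination and for the COMPASS, Dot1 and Paf1 factors, none passed over all probe sets or when adjusted over the list alone, and the median log2 difference was 0.04 (camera adjusted p = 0.971); it was 0.0098 without H2B K123R replicate 1 and negative after quantile normalization and cyclic loess. Of 23 genes for silencing and histone chaperone factors, POB3, a subunit of the FACT complex, rose 1.49-fold from 954 ± 52.3 to 1430 ± 128, and no other member passed (2 when adjusted over the list alone). That list's median was 0.08 and its mean 0.06, while its test pointed down (camera adjusted p = 0.962). The median was 0.0016 without H2B K123R replicate 1. Of 201 telomere-proximal genes, 21 rose and 8 fell (28 and 11 when adjusted over the list alone), with a median of 0.14 and no call (camera adjusted p = 0.334); PAD1 had the smallest p among them. Without wild-type replicate 1, 2 or 3 or H2B K123R replicate 3, no silencing gene and at most 4 telomere-proximal genes passed.

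The remaining lists were not called by camera. At most 1 gene of each passed without wild-type replicate 1, 2 or 3 or H2B K123R replicate 3. Of 28 iron regulon genes, 6 rose and 1 fell (9 when adjusted over the list alone), led by FIT2, with a median of 0.17, a camera adjusted p of 0.405 and a call by fry (adjusted p = 0.00921). Of 32 cell wall genes 3 rose, with GSC2 the strongest, and 3 fell (7 when adjusted over the list alone); their median was -0.10, their mean 0.0046 and the camera adjusted p 0.184, or 0.0439 without H2B K123R replicate 2, when the list was called lower. Without H2B K123R replicate 1 the cell wall median was -0.0047, the adjusted p 0.966 and the test pointed up. PAU3 was the only one of 8 flocculin and seripauperin genes that passed, rising from 173 to 295 (3 when adjusted over the list alone; camera adjusted p = 0.238, or 0.0427 without wild-type replicate 2; fry adjusted p = 0.0113). Of 24 heat shock chaperone genes 2 rose, among them CPR6 from 3577 to 4499 (5 when adjusted over the list alone; camera adjusted p = 0.238, or 0.0258 without wild-type replicate 3). Of 54 ribosome biogenesis genes 2 rose and 1 fell, the nucleolar protein gene NSR1, from 2904 to 2203 (3 when adjusted over the list alone; camera adjusted p = 0.238). Of 23 DNA damage response genes, UBI4 rose and 1 other fell (2 when adjusted over the list alone; camera adjusted p = 0.822). Of 10 galactose regulon genes only GCY1 passed, rising from 127 to 268 (1 when adjusted over the list alone; median -0.03, or -0.08 without H2B K123R replicate 1, mean 0.08, camera adjusted p = 0.785). Of 8 selectable marker genes, HIS3 rose and 1 other fell (2 when adjusted over the list alone; median -0.04, or 0.0068 without H2B K123R replicate 1, mean 0.05, camera adjusted p = 0.714). None of 16 phosphate starvation genes passed by either adjustment, adjusted over the list alone included (camera adjusted p = 0.195), and none of 13 hexose transporter genes passed over all probe sets (2 when adjusted over the list alone; camera adjusted p = 0.785).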

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

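All tests below were chosen after the results were seen, except that of the ribosomal protein genes without H2B K123R replicate 1 and the counts over other splits of the arrays; the rule for the test of level was rewritten after a first version, based on the percentile alone, had spoken against a shared difference.

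The 10 control probe sets for ribosomal RNA, which enter no comparison, had a mean log2 signal of 9.35 on the array of H2B K123R replicate 2, above the highest wild-type array, that of replicate 2 (8.44). The arrays of both groups had the same order, with replicate 1 lowest and replicate 2 highest: replicate 1 read 6.36 in wild type and 5.14 in H2B K123R, and replicate 3 read 6.99 and 7.09.

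Ribosomal protein genes were lower in H2B K123R by a median of -0.19. The compression of H2B K123R replicate 1 was not the whole cause, since the median was -0.12 without that array and both other mutant arrays lay below all wild-type arrays. A difference shared by all bright genes is consistent with most of the shift. Random lists of other genes matched on level had a median of -0.16 (95% between -0.18 and -0.10). The call ended after quantile normalization (median -0.03, quartiles -0.08 and 0.02) and cyclic loess (-0.06, quartiles -0.10 and -0.0031). Before them the median was -0.19 with quartiles -0.24 and -0.11. These methods remove such a shared difference, but could also remove a real fall of these genes, which are among the brightest. The lost call therefore does not tell the causes apart. The list lay at percentile 0.45 of the matched lists, so a small further shift, and an effect of the mutation on it, stay open.

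Probe sets for tRNAs were lower in H2B K123R, with a median log2 difference of -0.68. The array of H2B K123R replicate 1 alone did not account for this, since the median was -0.67 without it. A loss of small RNAs of any kind is unlikely, since snoRNA and snRNA probe sets had a median of 0.13. So is a fault common to all probe sets shared by families, since those that name no tRNA had a median of 0.0116. They read other families, so they do not test sharing among tRNAs. Among tRNA probe sets the median was -0.75 for the type shared by families and -0.42 for the other 17, so a part of the probe set type stays open. Most of the 17 are of another type that can also be shared. Only TRT2, TRR4 and YNCG0028W had a probe set of neither a shared nor an incomplete type. Their log2 differences were -0.45, -0.33 and -0.20, and none passed. Recovery of tRNA-sized molecules in extraction or labelling, which snoRNAs, being longer, do not test, stays open, as does an effect of the mutation or of the strain, none of which was tested.

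MFA1 and BAR1 fell and MF(ALPHA)1 and MF(ALPHA)2 rose, while the other 5 a-specific and 2 alpha-specific genes of the lists did not pass. With a block on the replicate number none of these calls held. AFB1, the a-factor barrier gene, was in neither list, so the means below leave it out. It fell, with a log2 difference of -1.24 (limma adjusted p = 0.0164), while all 4 genes of the alpha-specific list had positive differences. Counted with that list, it would lower the list's mean, so the difference below holds for the listed genes only. The mean of the alpha-specific minus that of the a-specific genes was 0.68 higher in H2B K123R on the log2 scale, and 0.66 higher without replicate 1, so that array alone did not account for it. The 4 probe sets for the alpha genes of the mating-type loci differed by -0.0901 (95% limits -0.27 and 0.09), so they showed no rise. Their median signals were 84.1 in wild type and 79.1 in H2B K123R, above the mouse control probe sets (at most 18.3). Whether these signals come from the silent alpha cassette alone is not known, so a small rise in its transcripts stays open. A share of alpha cells that only diluted the a cells would lower all a-specific genes by a common factor. Their differences varied beyond their residual spread (F = 10.2 on 6 and 24 degrees of freedom, and at least 7.31 without MFA1, ASG7 or H2B K123R replicate 1). Dilution by a share of alpha cells was therefore not the whole cause. The test does not cover a share that also changes expression in the a cells. A small share behind the rise of the alpha-factor genes alone, an effect of the mutation and another strain difference stay open.

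The 10 splits of the 6 arrays into 3 and 3 cannot give a share under 0.05. The real split was the only 1 of 10 that gave as many calls: 620 probe sets, against a highest other count of 0, and 105 at least 2-fold, against 0. For gene lists it was also 1 of 10, with 16 called lists against a highest other of 13, so that a call by camera with a preset correlation also occurred often in splits that mix the strains.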

How the results depend on the processing

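Cyclic loess was chosen after seeing the data. All 620 calls kept their sign under each alternative that tested them probe set by probe set. This was largely fixed in advance. The groups did not overlap for any of the 620, so leaving out or weighting arrays or changing the pseudocount could not turn a sign. The block, the level filters and the trend settings leave the differences unchanged. Only the normalizations and the median alignment could have turned one. The 620 calls became 2885 with array weights, which gave H2B K123R replicate 1 a weight of 0.181 and replicate 3 one of 4.52, and between 22 and 1023 when 1 array was left out; 610 of the 620 were among the 1023 calls without H2B K123R replicate 1. The 105 calls of at least 2-fold became 187 with a pseudocount of 1, 41 with 64, 59 above the median level (where fewer dim genes were tested), 166 with array weights and between 20 and 128 when 1 array was left out. The 16 called lists became 0 with an estimated correlation and lay between 12 and 18 otherwise. The cause of these changes was not tested, apart from the pseudocount, which by construction shrinks folds of dim genes. The fits with 1 array left out ranged from 22 to 1023 calls, so the smaller number of arrays alone does not account for them. MFA2, not called at -0.08, became 0.0325 after quantile normalization and 0.0036 after cyclic loess. With the replicate block 307 probe sets were called, of which 286 were among the 620; it changed no list's call and ended those of 22 named genes: ERC1, PRE4, RPN2, EGT2, MRP1, PRM4, PFK1, MFA1, BAR1, ATG14, PEP4, PRB1, MF(ALPHA)1, MF(ALPHA)2, ERG5, ERG11, IMD3, PAU3, NSR1, CPR6, CDC20 and GCY1. The mean of a gene's probe sets ended the calls of GSC2 and FUS3. Signal over background limits dim genes: JEN1, ATG14 and YNR064C in wild type lay within the range of the mouse control probe sets.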

Other observations

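The test of telomere-proximal genes was chosen after its counts were seen, and so were the small RNA classes; the tests of neighbouring genes and of gene length were set beforehand.

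Of 92 probe sets for tRNA genes, 45 were lower and none higher in H2B K123R, 86 differences were negative, and the median change was 1.60-fold. The tRNA median log2 signal was 7.62, 7.85 and 7.78 on the wild-type arrays and 6.75, 7.01 and 6.86 on the mutant arrays. The probe set of SUF1, a tRNA gene, fell from 102 ± 20.9 to 24.7 ± 6.67, and that of SUF17, another, fell from 252 ± 16.2 to 110 ± 9.92. Both probe sets are of the type shared by gene families, so these falls cannot be assigned to either gene with certainty. Of the 92 probe sets, 75 are of the type shared by gene families, with 42 lower and a median of -0.75. Many of these therefore read the same transcripts and are not independent. The other 17 had a median of -0.42 with 3 lower. These 3, and most of the 17, are of another type that can also be shared. Without wild-type replicate 1, 5 tRNA probe sets were called, without wild-type replicate 2 or 3 none was, and without H2B K123R replicate 3, 7 were, while the median stayed between -0.73 and -0.63 when any 1 array was left out.

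Among 63 snoRNA and snRNA probe sets, 6 were higher and none lower, 20 differences were negative, and the median was 0.13. SNR44 rose 1.88-fold from 1000 ± 26.0 to 1896 ± 93.7, SNR72 from 207 ± 29.4 to 476 ± 156, SNR61 from 138 ± 27.2 to 300 ± 65.3, SNR9 from 159 to 283, SNR64 from 32.9 to 64.9 and SNR6, the U6 snRNA, from 74.3 to 169. Without wild-type replicate 1, 2 or 3, or H2B K123R replicate 3, 1 of them was called. How well small RNAs were labelled was not measured. The signals of these and of the tRNA probe sets therefore need not follow RNA amounts.

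As a hypothesis, genes near chromosome ends may respond to H2B K123R more often than others. Of 201 telomere-proximal genes 29 were called (14.4%), against 426 of 5266 others (8.09%), an odds ratio of 1.92 (95% limits 1.23 and 2.89; Fisher's exact test, two-sided, p = 0.00375). The odds ratio was 1.67 without H2B K123R replicate 1 (Fisher's exact test, p = 0.00606) and 1.85 over genes read by probe sets not of a shared type (Fisher's exact test, p = 0.0132). This was 1 of 3 such tests of position and length, genes of one region are not independent, and calls went in both directions, 21 higher and 8 lower. Without wild-type replicate 3 none of the 201 was called, without wild-type replicate 2 there was 1, without wild-type replicate 1 there were 2 in each direction, and without H2B K123R replicate 3 there were 2 higher and 1 lower.

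Neighbouring genes may change together. Among 5467 protein-coding genes placed in order, 33 adjacent pairs were called in the same direction, 29 higher and 4 lower, where shuffled orders gave a median of 23 (permutation test, 10000 shuffles, p = 0.0219). Without H2B K123R replicate 1 there were 77 pairs against a median of 52 (permutation test, p = 0.00030). The annotated genes of 1 of the 33 pairs overlap. The pairs included HPF1 with ZPS1 (log2 differences 2.17 and 0.79) and PAD1 with FDC1 (625 to 305 and a log2 difference of -0.60); the last pair both act in decarboxylating phenylacrylic acids. Shared regulation of neighbours in both strains was not told from an effect of the mutation.

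Gene length did not go with the change. Across genes, which are not independent replicates, Spearman's rho of annotated length and log2 difference was -0.0045, and -0.0026 without H2B K123R replicate 1.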
